A study of Mus musculus with 9 samples.

How the data were processed

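RNA and 5hmC were measured in macrophages of Tet2 knockout and wild-type mice kept in M-CSF, at passage 0 per the labels. Groups and replicate numbers were taken from the submitters' sample labels: 2 knockout and 3 wild-type RNA libraries and 2 knockout and 2 wild-type 5hmC libraries, 9 in all. RNA values are counts per gene as the authors deposited them, from ribosomal-RNA-depleted total RNA per the labels. 5hmC values are counts per peak as the authors deposited them, from DNA enriched for biotin-tagged 5hmC per the labels. The submitters' processing notes name CASAVA 1.4, Trim Galore, STAR, BWA, MACS2 and HTSeq and the mouse build GRCm38. The role of each tool, the annotation release, the strand setting and the treatment of duplicate reads are not given in the sources used here. Peak names in the files show peaks called on merged knockout and on merged wild-type libraries and joined where they overlap: 1151 carry a knockout name, 7044 a wild-type name and 956 both. The numbers in those names run to 12299 for knockout and 56360 for wild type, of which 2107 and 8001 are listed, so the list is part of a longer one whose rule of choice is not given in the sources used here.

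Of 47731 genes in the RNA table, 47224 were matched to a symbol. Gene positions were taken from the RefSeq gene table of the same build, which gives starts and ends but no exons or strand. A peak was assigned to each gene whose body it overlapped, which held for 6379 of 9151 peaks. The design had also added 2 kb upstream, which needs the strand, so the main gene sums used the gene body alone. Peaks by promoter, exon and intron were replaced by peaks inside or outside a gene body. The motif test was not run, because no genome sequence was used here.

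Each assay was fitted apart with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The 2 knockout 5hmC libraries differed by less than sampling noise (chi-square per degree of freedom 0.575, p = 2.6e-73 for a value this low). They were therefore entered as 1 sample, the mean of their counts, which departs from the planned fit of 2 samples. The spread then comes from the 2 wild-type libraries alone. Normalised CPM are counts per 1000000 of the TMM-scaled library size, and plain CPM are per 1000000 counts in genes. Floors for a count of 0 use 3 counts per library and cover counting error only. Lists of genes were fixed before the data were examined, and 27 of 31 had the minimum of 5 tested members. They were tested with camera of limma 3.58.1 at the preset correlation of 0.01, and again with an estimated correlation and with fry, with adjustment over the lists. With an estimated correlation, camera takes its degrees of freedom from the libraries, which are few. A list can fail that run for this reason alone. Members were counted over all genes and adjusted over the list alone. Shares and overlaps were tested with two-sided Fisher's exact tests and the correlation across genes with 9999 permutations.

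Named RNA genes were Tet1, Tet2, Tet3 and Runx1, then genes past the threshold with a mean of at least 1 CPM and no overlap between genotypes, up to 10 in each direction by p. Predicted genes, clone names and pseudogenes were left out, and up to 4 called members of each list were added. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p under the same filters, no overlap included, were named. Named peaks were the 6 higher and 6 lower called peaks without overlap that had the smallest p, with called peaks in named genes. List members shown as examples were chosen after their values were seen, as were the genes named from the 5hmC sums. Some genes that the rule names are not reported here.

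The steps were tested on simulated counts drawn from the real means, library sizes and fitted dispersion (0.255 for RNA), with known fold changes. Of changed genes in the 14851-gene RNA step, 1.92% were recovered at 2-fold, 22.4% at 4-fold, 73.3% at 8-fold and 92.6% at 32-fold. In the step of 859 peaks the shares were 19.2%, 66.7% and 86.9% at 2-, 4- and 8-fold, and in the step of 1263 genes with 5hmC 20%, 73.0% and 72.2%. Small differences in RNA were therefore not detectable with these libraries. The simulation gave every gene of a step the same dispersion, so its shares need not hold for the real genes. In the real fit Mamdc2 (log2 -7.66) and Tmem154 (log2 -5.28) were not called (edgeR adjusted p = 0.138 and 0.137), so large differences were missed too.

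Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, a threshold of 0.1, a test against a fold of 1.2, a replicate block and leaving out each replicate. Those chosen after seeing the data were the knockout 5hmC libraries as 2 samples (also without a wild-type replicate) or summed, scaling to unplaced contigs and mitochondrial DNA, subsets of peaks or genes, and 2 kb on both sides of a gene. For the 5hmC gene sums, the correlation of the assays, the places of peaks and the 5hmC lists, most alternatives were also chosen after seeing the data. Intervals of the tests in the closing part are 95% intervals. Tables and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.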

Results

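Macrophages from Tet2 knockout and wild-type mice, kept in M-CSF (the growth factor that drives macrophage differentiation), were profiled by 2 assays. TET2 is an enzyme that oxidises 5-methylcytosine in DNA to 5-hydroxymethylcytosine (5hmC). Ribosomal-RNA-depleted total RNA was sequenced in 2 libraries labelled knockout and 3 labelled wild type. DNA enriched for biotin-tagged 5hmC was sequenced in 2 libraries of each genotype. The RNA libraries held 16053426 and 25479447 counts (knockout replicates 1 and 2) and 17569441, 51355576 and 56394358 counts (wild-type replicates 1, 2 and 3) in genes. The 5hmC libraries held 46230 and 42489 counts in the 9151 listed peaks for knockout and 42678 and 219116 for wild type. The labels do not say whether the libraries came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Fold changes are knockout over wild type throughout.

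The targeted gene was examined first. Tet2 (ENSMUSG00000040943; GRCm38 chromosome 3, 133463677 to 133545136) was at 232 and 126 counts per 1000000 counts in genes (CPM) in the 2 RNA libraries labelled knockout and at 86.2, 144 and 41.6 CPM in the 3 labelled wild type. The fitted log2 change was 0.91 ± 0.56 (SE; edgeR quasi-likelihood adjusted p = 0.520). Whole-gene counts therefore did not fall in the libraries labelled knockout, and they cannot tell which part of the gene was deleted. Every direction below rests on the labels. A feature of a knock-in sequence in the gene table (ENSMUSGKI000000001) had 1452 and 2245 counts in the libraries labelled knockout and 0 in all 3 wild-type libraries. The other of the 2 knock-in features (ENSMUSGKI000000002) had 1 and 3 counts against 0, 6 and 3, which does not separate the genotypes. The lower knockout level of the former, 88.1 CPM, was at least 516-fold higher than the highest level that a floor of 3 counts per wild-type library allows. On the knock-in sequence, the 5hmC peak at 615 to 1564 had 233 and 202 counts in the knockout libraries and 6 and 39 in the wild type. The other, at 5270 to 5649, had 49 and 41 against 0 and 1 and the smallest p of all tested peaks (edgeR adjusted p = 4.2e-27). The 1 listed 5hmC peak within Tet2 (chromosome 3, 133532150 to 133532451) had 0 counts in both knockout libraries, which allows up to 6.49 and 7.06 per 100000 peak counts. It had 3 and 18 counts in wild type, or 7.03 and 8.21 per 100000. Tet3 did not pass the test (log2 0.51 ± 0.58, adjusted p = 0.719), nor did Runx1 (log2 -0.40 ± 0.31, adjusted p = 0.602), by the same edgeR test. Tet1 had at most 0.426 CPM in any library and was not tested.

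The comparison of RNA levels asks which transcripts differ between knockout and wild-type macrophages. Only 2 of 14851 tested genes passed an adjusted p of 0.05 in edgeR, both higher in the libraries labelled knockout. The knock-in feature ENSMUSGKI000000001 was not among them, despite 1452 and 2245 counts against 0 in all wild-type libraries. Few calls therefore do not mean few differences. The 2 called are predicted genes whose names the naming rule leaves out, so they were named after their values were seen. Gm10260 (ENSMUSG00000069117) was at 80.3 ± 19.8 normalised CPM in knockout (SD, n = 2) and 0.254 ± 0.116 in wild type (SD, n = 3; edgeR adjusted p = 0.0429). Gm10036, a pseudogene on chromosome 18 (15832774 to 15833370), was at 40.4 ± 12.1 and 0.936 ± 0.0641 (edgeR adjusted p = 0.0429). Pseudogenes can share reads with near-identical copies, so both counts are uncertain. No gene fell past the threshold, while 883 genes were higher and 1167 lower at an unadjusted p under 0.05. DESeq2 called 1234 genes, 509 higher and 725 lower, limma-voom called 1 (neither of these 2), and edgeR called 0 with total-count scaling and whenever any 1 library was left out.

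With fewer than 5 calls in each direction, the rule named the 5 genes with the smallest unadjusted p on each side, none of which passed the adjusted threshold in edgeR. Among the higher ones, Tnf, a central inflammatory cytokine, was at 214 ± 9.38 normalised CPM in knockout (SD, n = 2) and 29.4 ± 8.71 in wild type (SD, n = 3), a fitted 7.27-fold difference (edgeR adjusted p = 0.137). Ell2, a transcription elongation factor, stood 3.93-fold higher, and Ppp2r1b, a scaffold subunit of protein phosphatase 2A, 4.22-fold. Hmga1b had a log2 difference of 2.51, with a count that may be shared with its near-identical relatives. Among the lower ones, Sulf2, an extracellular sulfatase, was at 6.31 ± 0.146 and 74.8 ± 24.0 normalised CPM. Mamdc2 had a log2 difference of -7.66, Tmem154 of -5.28 and Mfsd6 of -2.18. Rpl29, a ribosomal protein gene with many pseudogene copies, had -3.20 (edgeR adjusted p = 0.0857, the lowest of the 10). All 10 had no overlap between the knockout and wild-type libraries because the rule required it. Of all tested genes 36.2% had none, against 20% by chance.

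Interferon-stimulated genes, the antiviral response set, had a uniform direction. All 25 tested members had a higher fitted level in the libraries labelled knockout, with a median log2 of 2.01. Isg15, a ubiquitin-like interferon product, was at 56.5 and 55.0 normalised CPM in knockout against 2.26, 15.5 and 5.62 in wild type. Zbp1, a nucleic acid sensor, was at 77.9 and 43.9 against 2.39, 15.3 and 5.38. The list passed camera with its preset correlation (adjusted p = 6.2e-17) and not with an estimated correlation (adjusted p = 0.678). No member passed over all genes and 0 passed adjusted over the list alone in edgeR, with 13 at an unadjusted p under 0.05 and 9 called by DESeq2. Adjusted over the list alone, 8 rose without wild-type replicate 1, 23 without wild-type replicate 2 and 0 without wild-type replicate 3. The median log2 was 1.63, 3.18 and 1.79 in these fits, and 1.69 and 2.25 without knockout replicate 1 and 2.

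Of 22 inflammatory cytokines and mediators, 18 had a higher fitted level, with a median log2 of 1.94 (camera adjusted p = 1.3e-08; adjusted p = 0.678 with an estimated correlation). No member passed over all genes and 3 rose when adjusted over the list alone: Tnf, the chemokine gene Ccl3 and Ptges, a prostaglandin E synthase. Ccl3 was at 274 and 197 normalised CPM in knockout and 50.3, 42.7 and 79.8 in wild type. Il1b did not pass, at 19.2 and 5.06 against 0.752, 0.864 and 4.26. Adjusted over the list alone, 1 rose without either knockout replicate, 5 without wild-type replicate 1, 8 without replicate 2 (where 1 fell) and 15 without replicate 3, where 20 of 21 members were higher and the median log2 was 2.87.

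Genes of the lysosome and of sterol and lipid metabolism lay on the other side. Of 24 lysosome genes, 23 had a lower fitted level in the libraries labelled knockout (median log2 -0.95, camera adjusted p = 6.2e-07, and 0.766 with an estimated correlation). Wild-type replicate 1 carried part of this. The list had a mean log2 level of 9.98 there, 8.98 and 9.08 in wild-type replicates 2 and 3, and 8.34 and 8.53 in knockout. Without wild-type replicate 1 the median was -0.64, with 22 members lower (camera adjusted p = 1.1e-05). Ctsd, a lysosomal protease, was at 3213 and 3920 normalised CPM in knockout and 24364, 6402 and 12136 in wild type, and Lamp1, a membrane protein of the lysosome, at 700 and 942 against 3367, 1499 and 1828. All 22 cholesterol synthesis genes had a lower fitted level (median log2 -1.26, camera adjusted p = 1.7e-05; adjusted p = 0.784 with an estimated correlation). Wild-type replicate 3 carried much of this: without it the median was -0.46, with 19 members lower (camera adjusted p = 0.0171). Of 16 LXR targets and lipid handling genes, 13 had a lower fitted level (median log2 -1.02, camera adjusted p = 0.0023; adjusted p = 0.735 with an estimated correlation). Fabp4, a fatty acid binding protein, was at 5.19 and 6.28 normalised CPM in knockout and 244, 37.0 and 68.8 in wild type. No member of these 3 lists passed over all genes or adjusted over the list alone in edgeR, with 7, 4 and 5 at an unadjusted p under 0.05, while DESeq2 called 6, 1 and 4. Adjusted over the list alone, 1 LXR target fell without wild-type replicate 1 and 2 without replicate 2.

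Ribosomal protein genes had a small shift, with 22 of 24 lower (median log2 -0.28, camera adjusted p = 0.0098; adjusted p = 0.796 with an estimated correlation). Without knockout replicate 1 the median was -0.05 and the list did not pass (camera adjusted p = 0.573), nor did it without wild-type replicate 3 (camera adjusted p = 0.0845), whereas without knockout replicate 2 all 24 were lower (median log2 -0.58, camera adjusted p = 3.6e-06). It did not pass with the replicate block either (camera adjusted p = 0.114). Of 10 alternative activation genes, 7 had a lower fitted level (median log2 -2.09, camera adjusted p = 0.0478; adjusted p = 0.678 with an estimated correlation). Mrc1, the mannose receptor, was at 132 and 134 normalised CPM against 267, 689 and 1502, whereas Il10 was at 57.7 and 24.9 against 0.752, 8.56 and 0.618. This list did not pass without knockout replicate 1 or 2 (camera adjusted p = 0.232 and 0.139). No member of the ribosomal protein or alternative activation list passed over all genes or adjusted over the list alone in edgeR, with 3 and 5 at an unadjusted p under 0.05, while DESeq2 called 1 and 5. Adjusted over the list alone, 6 alternative activation genes fell without wild-type replicate 1, 1 rose and 2 fell without replicate 2, and 1 fell without replicate 3.

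Osteoclast genes were listed because the series concerns osteoclast differentiation, and they showed no common direction. Of 22 tested members, 10 had a higher and 12 a lower fitted level (camera adjusted p = 0.463), 0 passed over all genes or adjusted over the list alone in edgeR (7 at an unadjusted p under 0.05), and DESeq2 called 5. Mmp9, a matrix protease of osteoclasts, was at 755 and 634 normalised CPM in knockout and 1.57, 68.4 and 3.39 in wild type. Tnfrsf11a, the RANK receptor, was at 340 and 287 against 146, 177 and 111. Itgb3, an integrin of the resorbing cell, was at 1.89 and 4.15 against 53.1, 15.2 and 21.1. Negative regulators of osteoclast formation divided into 7 higher and 7 lower (camera adjusted p = 0.585). Among 17 RUNX and myeloid transcription factors (camera adjusted p = 0.395), 3 fell when adjusted over the list alone, among them Lmo2 and Cebpa, and 0 did without either knockout replicate. Cebpa was at 14.7 and 26.6 normalised CPM in knockout against 248, 72.7 and 112 in wild type. Without wild-type replicate 2, 1 osteoclast gene rose and 1 fell, adjusted over the list alone, and 2 negative regulators fell without wild-type replicate 1 or 2. Macrophage identity genes divided into 9 higher and 11 lower (camera adjusted p = 0.971), of which 2 rose and 4 fell without wild-type replicate 1 and 4 rose and 5 fell without replicate 2, adjusted over the list alone, and genes of the TET enzymes and DNA methylation machinery into 10 and 7 (camera adjusted p = 0.757).

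Markers of other cell types also differed between libraries. Collagen genes were abundant in wild-type replicate 3 alone: Col1a1 was at 1214 CPM there and at most 0.436 CPM in the other 4 RNA libraries, and 11 of 14 stromal and osteoblast markers were at least 10 times the highest other library. That list did not pass (camera adjusted p = 0.371), except without knockout replicate 1 (camera adjusted p = 0.0375). Its median log2 was -3.97 with all libraries and 2.67 without wild-type replicate 3, where only 3 members were tested, all of which rose adjusted over the list alone. Of the list calls made with 1 library left out, none held with an estimated correlation (smallest adjusted p = 0.50), a run with still fewer degrees of freedom. B cell markers were low but higher in knockout: 4 of 5 tested members rose when adjusted over the list alone, with 0 passing over all genes (camera adjusted p = 2.0e-04; adjusted p = 0.678 with an estimated correlation). Cd79b, part of the B cell receptor, was at 16.4 and 9.71 normalised CPM against 0.957, 2.72 and 0.217. Adjusted over the list alone, 4 of 6 tested members rose without wild-type replicate 1 and 3 of 4 without wild-type replicate 2. Without wild-type replicate 3, 3 of 4 rose and 1 fell. The median log2 was 5.21 with all libraries and 1.24 without knockout replicate 1, where 2 of 4 tested members had a higher fitted level. All 6 dendritic cell markers had a higher fitted level (camera adjusted p = 0.0191; adjusted p = 0.678 with an estimated correlation), with Batf3 at 14.4 and 5.29 against 2.60, 3.11 and 0.936. All 5 megakaryocyte markers had a lower one (camera adjusted p = 0.0283; adjusted p = 0.678 with an estimated correlation), of which Vwf fell when adjusted over the list alone, and the list did not pass without either knockout replicate or wild-type replicate 3. With the replicate block neither the dendritic nor the megakaryocyte list passed (camera adjusted p = 0.0590 for both). Cell cycle genes had a mean log2 level of 3.36 in wild-type replicate 1 and 5.80 to 6.98 in the other libraries. With all libraries 15 members were higher and 15 lower (camera adjusted p = 0.292). All 30 were lower without wild-type replicate 1 (camera adjusted p = 8.7e-04), whereas 28 were higher without knockout replicate 1 or wild-type replicate 2 and 26 without wild-type replicate 3 (camera adjusted p = 0.0030, 0.0157 and 0.0462).

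**Figure D1:**
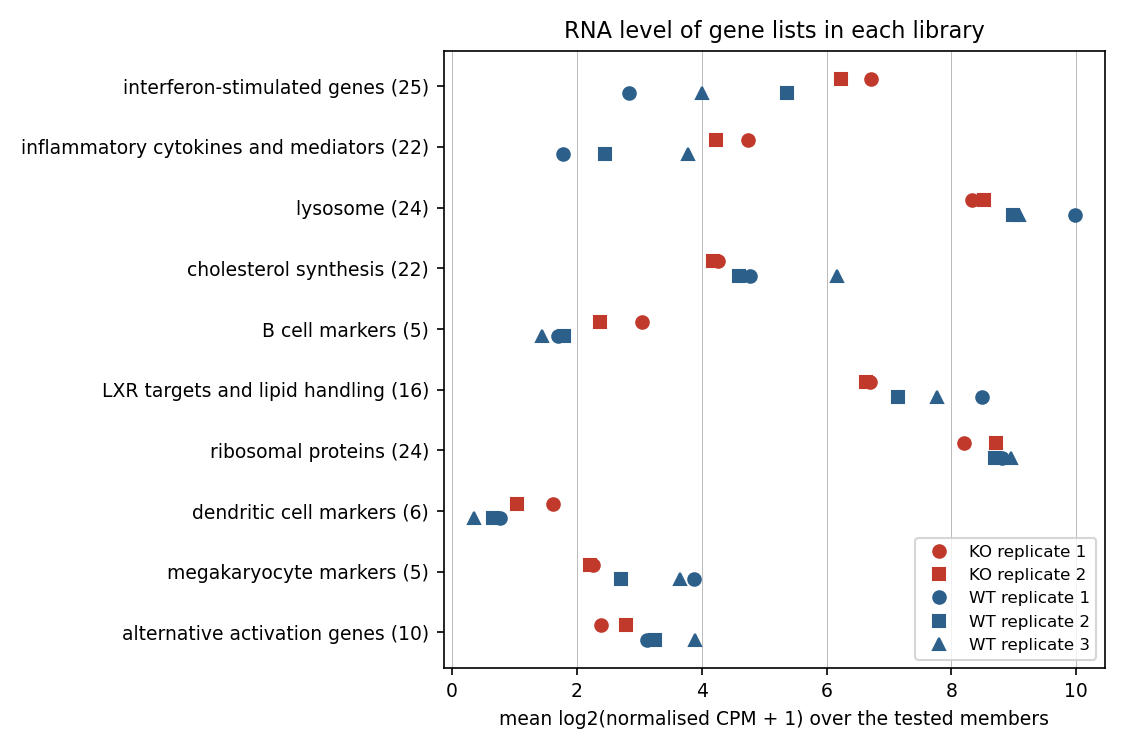
Mean log2(normalised CPM + 1) over the tested members of the 10 gene lists past the camera threshold, one point per RNA library, with the number of tested members in brackets. For interferon-stimulated genes both knockout libraries (6.71 and 6.24) lie above the 3 wild-type libraries (2.83, 5.37 and 4.01).

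The 5hmC comparison asks where 5hmC differs between the genotypes. The 2 knockout libraries differed by less than the sampling noise (chi-square per degree of freedom 0.575 over 2544 peaks), whereas the 2 wild-type libraries differed by more (1.2). The knockout libraries were therefore counted as 1 sample, the mean of their counts, which is assumed to vary like wild type. Of 859 tested peaks, 169 passed in edgeR, 154 higher and 15 lower in the libraries labelled knockout. The filter kept 423 of 7044 peaks called in wild type, 296 of 956 called in both and 140 of 1151 called in knockout. Most peaks where a loss would show were therefore not tested. Peaks called in wild type held 40.9% and 41.0% of knockout counts and 73.5% and 77.8% of wild-type counts, a difference that the calling itself favours. Their median count was 2 in each knockout library. The direction followed the genotype in which a peak had been called: 114 of 140 peaks called in knockout and 40 of 296 called in both were higher, and 15 of 423 called in wild type were lower. A peak chosen for its signal in 1 genotype favours that direction, so this is not independent evidence. Without knockout replicate 1 the fit called 157 higher and 77 lower peaks, and without knockout replicate 2 156 and 29. Among peaks called in both genotypes and fitted alone, 18 passed, all of them higher. DESeq2 called 71 peaks, all higher, so it kept none of the 15 lower ones.

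The balance of higher and lower peaks depended on several choices. TMM takes most peaks as unchanged, so a loss of 5hmC at all peaks alike would not be seen. Other scalings of the same peaks gave 133 higher and 20 lower (total count), 161 and 12 (DESeq2 size factors in edgeR) and 112 and 38 (loess). Entering the knockout libraries as 2 samples, as the design was first written, called 303 of 480 tested peaks, 152 higher and 151 lower, and a fit of chromosome peaks alone called 112 and 42. Scaling to the counts on unplaced contigs and mitochondrial DNA lowers the log2 of all peaks together, with a median of -2.87 in place of -0.25, and called 7 higher and 590 lower. It sets to no change sequences that took a larger share of the knockout libraries. Unplaced contigs held 6.22% and 6.17% of peak counts in knockout against 1.49% and 0.871% in wild type. Of the peaks there, 40 of 43 on contigs and 4 of 4 on mitochondrial DNA were called higher.

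**Figure D2:**
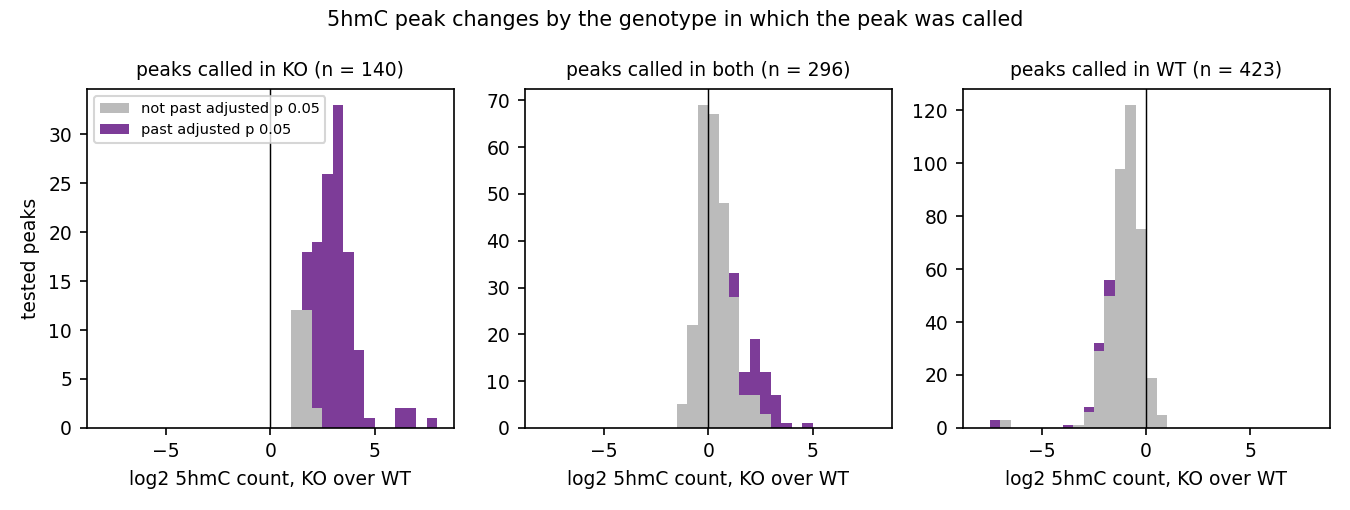
Histograms of the log2 5hmC count ratio, knockout over wild type, for the 859 tested peaks, divided by the genotype in which the peak was called, with peaks past an adjusted p of 0.05 in purple. Peaks called in knockout (140) lie to the right of 0 and most peaks called in wild type (423) to the left.

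**Figure D3:**
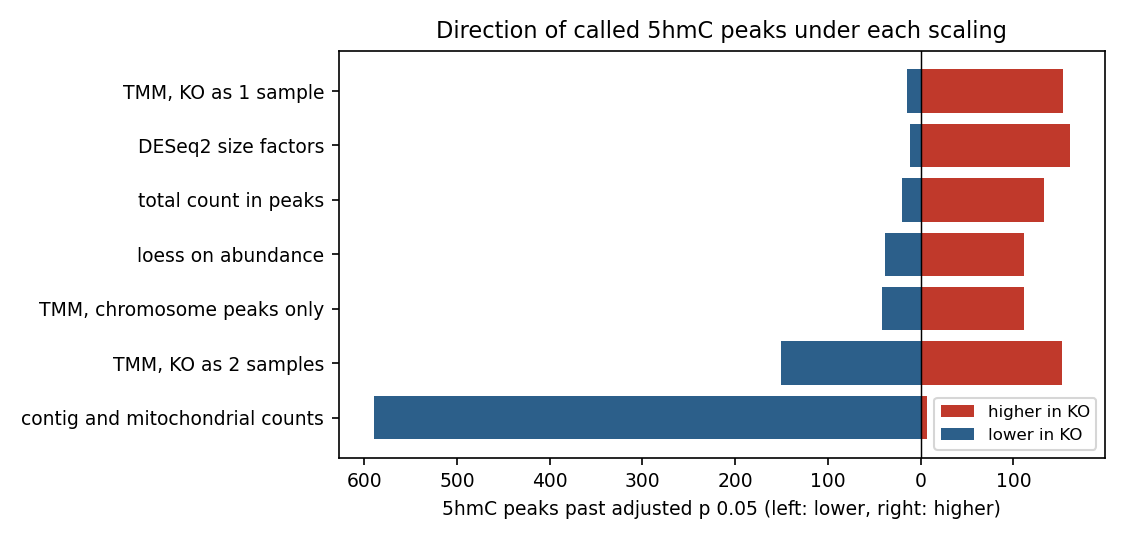
Number of 5hmC peaks past an adjusted p of 0.05 under 7 scalings or replicate choices, with peaks higher in knockout to the right and lower to the left. Calls go from 154 higher and 15 lower with TMM to 7 higher and 590 lower when scaled to contig and mitochondrial counts.

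Outside the knock-in sequence, the peak with the smallest p among those higher in knockout lay on chromosome 9 (24541893 to 24542300, 14747 bp from Dpy19l2), with 49 and 48 counts in knockout and 3 and 18 in wild type (log2 3.80 ± 0.39 SE). A peak inside Tet1 (chromosome 10, 62812496 to 62813387) had 43 and 31 counts against 0 and 2. A peak inside Tet3 (chromosome 6, 83453967 to 83454374) had 17 and 15 against 3 and 31 (log2 1.58 ± 0.60, edgeR adjusted p = 0.0471). That call was lost without knockout replicate 1 or 2 (adjusted p = 0.0878 and 0.0780), with total-count scaling (0.156), by DESeq2 (0.283), in a test against a fold of 1.2 (0.0574), with the knockout libraries as 2 samples (0.0532) and in the fit of chromosome peaks alone (0.167). Others were on chromosome 9 (3017374 to 3017591), on chromosome 17 within 2700054A10Rik (13551746 to 13552413) and on an unplaced contig. Of the lower peaks, that with the smallest p lay on chromosome 6 (125540244 to 125541309), 11639 bp from Vwf, with 5 and 5 counts against 25 and 100 (log2 -2.02 ± 0.55). A peak in Exoc4, a subunit of the exocyst complex (chromosome 6, 33823604 to 33824368), had 2 and 1 counts against 16 and 71. Lyst, a regulator of lysosome traffic, held one (chromosome 13, 13637659 to 13638384) with 0 and 1 against 10 and 39. Eepd1 (chromosome 9, 25570023 to 25570861) had 4 and 3 against 12 and 88, and the others were on chromosome 15 within Gm46496 (5355352 to 5356072) and on chromosome 3 (151948270 to 151948738). In DESeq2 4 of these 6 lower peaks had adjusted p from 0.369 to 0.831 and the others had none. In edgeR the Lyst peak was lost with total-count scaling (adjusted p = 0.0547), those near Vwf and in Exoc4 and Eepd1 with no filter (adjusted p = 0.141, 0.0578 and 0.133), and that in Eepd1 by limma-voom (adjusted p = 0.136). None of the 5 listed peaks in Runx1 had enough counts to be tested. Exons, introns and promoters were not assigned, because gene starts and ends but no exons or strand were at hand.

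With the counts of all peaks in a gene body summed, 126 of 1263 genes passed in edgeR, 106 higher and 20 lower in the libraries labelled knockout (117 and 36 without knockout replicate 1). Examples chosen after their values were seen are, among the higher genes, Ctsb, a lysosomal protease (59 and 52 counts against 11 and 13, log2 4.14 ± 0.33), Vim, an intermediate filament protein (log2 3.24 ± 0.27), Lyz2, a lysozyme (log2 2.19 ± 0.32), and Acp5, an osteoclast phosphatase (log2 3.37 ± 0.61). Among the lower genes they are Magi2, a scaffold protein (10 and 6 counts against 30 and 143, log2 -1.50 ± 0.43), Etv6, a transcription factor (log2 -1.22 ± 0.41), and Lipa, the lysosomal acid lipase (log2 -2.41 ± 0.82). Total-count scaling gave 72 higher and 91 lower, contig and mitochondrial scaling 1 and 270, and the knockout libraries as 2 samples 192 and 133. Most calls stayed higher with DESeq2 size factors in edgeR (108 higher and 18 lower) and with loess (47 and 8). DESeq2 called 21 genes, all higher. Lysosome genes (7 with peaks, median log2 1.55, camera adjusted p = 0.0129) and osteoclast genes (7, median log2 1.66, adjusted p = 0.0362) were the 2 lists with at least 5 tested members, and both had adjusted p = 0.308 with an estimated correlation. With 1 averaged knockout and 2 wild-type samples, that run has almost no degrees of freedom. It gave both lists the same estimated correlation, 0.0476, so it cannot decide. In the lysosome list 4 genes rose, Ctsb, Ctsd, Psap and Grn, and 1 fell, Lipa. In the osteoclast list 3 rose, Acp5, Ctsk and Fos. Ctsb, Ctsd, Grn, Lyz2, Acp5, Ctsk and Fos had 1 listed peak each, so their sums are counts of a single peak, while Psap and Lipa had 2. The choice of peaks by the genotype in which they were called therefore bears on these sums and lists too.

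The share of chromosome peaks inside a gene body was 65.7% among the 108 higher peaks, 66.7% among the 15 lower peaks and 74.2% among the 687 not called (two-sided Fisher's exact tests, adjusted p = 0.159 and 0.553). With the knockout libraries as 2 samples it was 61.3% among higher peaks and 77.7% among those not called (Fisher's exact test, adjusted p = 0.0082).

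The last comparison asks whether the same genes differ in both assays. Of 1050 genes tested in both, 0 were called in both by edgeR, where no gene was called in RNA and 79 were higher and 18 lower in 5hmC. At an unadjusted p under 0.05 in both assays 44 genes were shared. Higher in both were 10 genes (13.1 expected from independent lists), lower in both 10 (9.46 expected), lower in RNA and higher in 5hmC 19 (21.8 expected), and higher in RNA and lower in 5hmC 5 (5.70 expected). Each had an adjusted p of 1 by Fisher's exact test. Those lower in RNA and higher in 5hmC included Ctsd, Gpnmb and Cd68, chosen after their values were seen. Across the 1050 genes Spearman's rho was 0.0043 (two-sided permutation p = 0.890) and Pearson's r was -0.033, and genes are not independent replicates.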

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

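The tests of peak position, of gain along the whole gene and of the segment around Tet2 were written before their results were seen, and the tests of expression level, shared pseudogene reads, depth, other cells and a wrong label were chosen only after the result was seen. The requirement that a whole 95% interval lie past a bound before an explanation was set aside was also chosen after the values were seen, and was applied to every test that has an interval.

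Signals appeared in sequences outside the main measurement. Of 2 knock-in features, ENSMUSGKI000000001 was at 90.4 and 88.1 CPM in the RNA libraries labelled knockout and at 0 counts in the 3 wild-type libraries, whereas ENSMUSGKI000000002 had 1 and 3 counts against 0, 6 and 3. Unplaced contigs held 6.22% and 6.17% of 5hmC peak counts in knockout, against 1.49% and 0.871% in wild type. Mitochondrial DNA held 0.757% and 0.873%, against 0.248% and 0.0826%.

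Among chromosome peaks inside a gene with a matched RNA level, those higher in knockout lay more often in abundantly transcribed genes. Of 62 such higher peaks, 32 (51.6%) were in genes of the highest RNA levels (above 142 CPM), against 123 of 464 not called (26.5%). The other peaks were not counted, so 51.6% is not a share of all 154 higher peaks. RNA or cDNA reads in the knockout 5hmC libraries are a candidate explanation. In genes longer than 10 kb, 7 of 39 higher peaks lay within 1 kb of a gene end, against 12 of 420 not called (odds ratio 7.44, 95% interval 2.29 to 22, Fisher's exact p = 4.4e-04), which that explanation needs, although promoter or gene-end background in the enrichment would give the same. The ratio of median RNA levels, 2.26 (0.898 to 4.87), does not decide between its predictions. Of all 154 higher peaks 114 were called in knockout, whereas 0 of the 423 tested peaks called in wild type were higher. Both comparisons therefore also contrast peaks called in different genotypes, which they do not separate from RNA level or position. With genes of the highest RNA levels left out, 88 genes passed in 5hmC, 72 higher and 16 lower (81.8% higher, against 84.1% with all genes). That excess depends on the scaling. Over all genes DESeq2 size factors in edgeR gave 108 higher and 18 lower and loess 47 and 8. Total-count scaling gave 72 and 91, and contig and mitochondrial scaling 1 and 270. The fit without the genes of the highest RNA levels was made with TMM alone, so it does not decide either. A gain of 5hmC along the whole gene, the biological alternative, was not settled either: 22 wild-type-called peaks in those genes differed from others by a median log2 of -0.0132 (-0.51 to 0.48), and the genotypes cannot be told apart from a difference in library preparation.

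The 2 genes called in RNA are a predicted gene and a pseudogene, and ribosomal protein genes had lower fitted levels. Pseudogenes as a class were not over-represented among the 300 genes with the smallest p (odds ratio 0.854, 0.479 to 1.42). This does not decide on shared reads, for the class or for the 2 called genes. The test did not match genes by RNA level and counted genes with pseudogene copies, such as Rpl29, as coding. It left out Gm10260, which has no annotated gene type. The tests of library depth do not decide. A first version gave 0.0158, against depth, on pseudogenes chosen by a small p, which made it void. Its replacement over all 846 tested pseudogenes turned this round: the shallow wild-type replicate 1 showed 0.764 (0.308 to 1.71) of the knockout libraries' median log2, but both medians share wild-type replicates 2 and 3, which alone can put the ratio above 0. With separate wild-type libraries in the medians it was 0.286 (0.0402 to 0.591) or 5.90 (-28.7 to 33.2). For a segment around Tet2 from another strain, 2 of 67 tested genes within 10 Mb were among the 300 (odds ratio 1.38, 0.163 to 5.23), too few to decide. Genotype itself stays open as an untested explanation.

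Wild-type RNA replicate 3 held stromal transcripts: Col1a2 was at 2373 CPM and Sparc at 605 CPM, and 11 of 14 written markers were at least 10 times the highest other library. Stromal or osteoblast cells in that culture may be their source, and the markers needed for that are there. A library of another cell type under a wrong label is argued against by 20 macrophage identity genes, whose median log2 was -0.22 (-0.87 to 0.68) relative to wild-type replicates 1 and 2. No biological explanation was tested, since the design gives none.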

How the results depend on the processing

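For RNA and for 5hmC peaks, the fits without 1 replicate and with another scaling of the total count, filter, test or block were planned. Tests chosen only after the result was seen were those with the knockout 5hmC libraries as 2 samples or summed, contig and mitochondrial scaling, subsets of peaks or genes and 2 kb sides. So were, for 5hmC genes, all but total-count scaling and leaving out a knockout replicate, for the correlation of the assays all alternatives printed here, and for peak places and 5hmC lists other scalings and samples. Among single genes, peaks and lists under all alternatives, 517 values kept direction and side of the threshold, 23 newly passed, 50 no longer passed and 32 turned direction, of which 1 is a peak and the others are medians of lists that had not passed with all libraries. Except where the setting itself shows it, the cause was not tested.

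For RNA genes (2 called), total-count scaling and every fit without 1 replicate called 0 (from 0 to 0, with 595 to 2510 at an unadjusted p under 0.05), limma-voom 1, an adjusted p of 0.1 gave 4, and DESeq2 called 1234 with most lower (509 higher, 725 lower; both edgeR genes were among them). Deviations from the group means showed no clear pairing by replicate number (correlations of same-numbered libraries 0.115 and -0.0469 in RNA and 8.8e-04 in 5hmC). The check is weak, because the deviations of 2 knockout libraries mirror each other. In 5hmC it could not show pairing, since the knockout libraries differed by less than sampling noise. The replicate block called 0 RNA genes (1999 at an unadjusted p under 0.05), and with the knockout libraries as 2 samples it called 258 peaks and 308 genes with 5hmC. For gene lists, 10 passed camera and 0 passed with an estimated correlation, a run with few degrees of freedom, or with fry. Leaving out 1 replicate gave 8 to 13 with the preset correlation. The replicate block gave 9: the dendritic, megakaryocyte and ribosomal protein lists were lost, B cell markers had no set test, and the cell cycle, hypoxia and endothelial lists were gained. The cell cycle median of about 0 became -0.51 without wild-type replicate 1, ranged from -0.67 to 0.52 over all fits without 1 replicate, and was 0.0091 with DESeq2 size factors and 1.26 (camera adjusted p = 4.2e-05) with the replicate block, which leaves out wild-type replicate 3. Tet2 kept its sign without any 1 library (0.41 to 1.30).

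The other lists whose median changed sign passed neither with all libraries nor in the fit that changed it. Without 1 replicate the medians ranged from -0.15 to 1.19 for endothelial markers, -0.22 to 0.45 for hypoxia and glycolysis, -0.74 to 0.022 for immediate early genes, -0.57 to 0.063 for matrix genes, -0.055 to 0.45 for mitochondrially encoded genes and -0.55 to 0.42 for monocyte markers. They ranged from -3.53 to 1.90 for myeloid progenitor markers, -0.21 to 0.14 for negative regulators of osteoclast formation, -2.25 to 3.83 for neutrophil markers, -0.75 to 0.31 for osteoclast genes, -0.49 to 0.13 for RUNX and myeloid factors and -0.12 to 0.15 for TET enzymes and DNA methylation. With the replicate block they were 0.10 for immediate early genes, 0.069 for matrix genes, -0.046 for mitochondrially encoded genes, 0.058 for negative regulators and 0.14 for RUNX factors. Negative regulators were at 0.0081 with total-count scaling and 0.012 with DESeq2 size factors.

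For 5hmC peaks (169 called), DESeq2 called 71 (all higher), no filter 435 and the stricter filter 0 of 39 (0 at an unadjusted p under 0.05). The stricter filter needed 50 counts in at least 2 samples. A peak or gene strong in knockout alone, entered as 1 sample, could not pass it. Its 0 calls therefore say nothing about such peaks or genes. The knockout libraries as 2 samples gave 303, summed 838, peaks called in both genotypes 18, and without a knockout replicate 185 to 234, with lower peaks going from 15 to 29 and 77. Contig and mitochondrial scaling gave 597, nearly all lower, with the Tet3 peak at -1.10, but it lowers all peaks together (median -2.87 against -0.25), which says nothing particular about that peak. For 5hmC genes (126 called), DESeq2 called 21, no filter 19, the stricter filter 0 of 17 (0 at an unadjusted p under 0.05), limma-voom 205, loess 55, 2 knockout samples 325, summed 445, and without a knockout replicate 152 to 153. Total-count scaling gave 163 and contig scaling 271, both mostly lower. The share of higher peaks in gene bodies was 61.3% with 2 knockout samples. An unadjusted p gave 44 genes in both assays. Spearman's rho across genes was -0.030 with the replicate block and 2 knockout samples, -0.022 without wild-type RNA replicate 3 and -0.016 with no filter, each near 0 (permutation p = 0.419, 0.481 and 0.371). For 5hmC lists, 0 of 2 passed with an estimated correlation or fry, which had too few samples to decide, and 1 with 2 knockout samples.

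With the knockout libraries as 1 sample, 5hmC fits without a wild-type replicate leave no residual degrees of freedom. With them as 2 samples, whose spread is then the only one, such fits called 505 peaks (241 higher, 264 lower) and 366 genes (181 and 185) without wild-type replicate 1, and 331 peaks (200 and 131) and 0 genes (303 at an unadjusted p under 0.05) without replicate 2. Promoter width, 2 kb upstream and motif alternatives were not run. Low counts limit the 5hmC result: 859 of 9151 peaks passed the filter in the main fit. That number depends on how the knockout libraries are entered as well as on depth. It was 480 with them as 2 samples and 5750 with them summed.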

Other observations

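The hypotheses weighed above are the only ones tested, and the fits without 1 library named here were planned; the count of genes in the MHC region is a test chosen only after the result was seen. No list call made without 1 library held with an estimated correlation (smallest adjusted p = 0.50), a run with few degrees of freedom.

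Matrix and adhesion genes divided by member. Adjusted over the list alone, Itgax, Mmp12, Timp2 and Mmp19 fell and Itga5 rose in the libraries labelled knockout, with 0 of 18 passing over all genes in edgeR (5 at an unadjusted p under 0.05, 5 called by DESeq2). Itgax, an integrin of dendritic cells and macrophages, was at 2.81 and 3.69 normalised CPM in knockout and 271, 162 and 66.5 in wild type. Mmp12, the macrophage elastase, was at 60.3 and 112 against 843, 698 and 1337. Itga5, a fibronectin receptor subunit, was at 251 and 196 against 99.2, 90.9 and 76.5. The list did not pass (camera adjusted p = 0.0960), but did without wild-type replicate 1 or 2 (camera adjusted p = 0.0039 and 0.0149), and 0 members passed without either knockout replicate. Both of those fits keep wild-type replicate 3, the library with collagen transcripts, where the list had a mean log2 level of 8.25, against 6.32 to 6.52 in the others. Without that replicate 3 members rose and 4 fell, the median log2 was 0.063 and the list did not pass (camera adjusted p = 0.489).

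Of 18 hypoxia and glycolysis genes (camera adjusted p = 0.292), Ndrg1 and the hexokinase gene Hk2 rose and the growth factor gene Vegfa fell, adjusted over the list alone. Ndrg1 was at 1698 and 834 normalised CPM against 88.3, 109 and 34.2, and Vegfa at 5.37 and 8.83 against 117, 38 and 108. No member passed without either knockout replicate. The list passed without knockout replicate 1 (camera adjusted p = 0.0045) and wild-type replicate 3 (0.0118) and with the replicate block (0.0067). Among 19 immediate early and stress genes (camera adjusted p = 0.109), Egr2, a transcription factor, fell adjusted over the list alone, at 2.14 and 2.17 normalised CPM against 89.7, 25.5 and 32.9, though not without either knockout replicate. That list passed without knockout replicate 1 (camera adjusted p = 0.0266) or wild-type replicate 2 (1.4e-04). Of 20 chemokine and cytokine receptors, 6 had a higher and 14 a lower fitted level (camera adjusted p = 0.253). Adjusted over the list alone, 1 receptor rose, against 0 without knockout replicate 2, 1 rising and 1 falling without wild-type replicate 2, and 2 rising and 9 falling without wild-type replicate 3. Among 6 endothelial markers (camera adjusted p = 0.168) Pecam1 rose, adjusted over the list alone, though not without knockout replicate 1 or wild-type replicates 1 or 2. The endothelial list passed without wild-type replicate 3 and with the replicate block (camera adjusted p = 0.0414 and 0.0171).

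Of 12 MHC class II and costimulation genes (camera adjusted p = 0.292), H2-DMb2 rose and its neighbour H2-DMb1 fell, adjusted over the list alone. They are paralogs that can share reads, so both counts are uncertain. Without wild-type replicate 3, 1 member rose, 3 fell and the list passed (camera adjusted p = 0.0432), whereas no member passed without any other single library. In the MHC region (chromosome 17, 33 to 38 Mb), 11 of 147 tested genes were among the 300 with the smallest p (odds ratio 3.72, Fisher's exact p = 3.9e-04). Tnf, already named for its small p, lies in this window (35199367 to 35202007). The region was chosen from these same data and its genes are not independent, so this p-value is not separate evidence.

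Other lists did not pass camera: neutrophil markers (11 tested, 8 higher, adjusted p = 0.292), monocyte markers (8 tested, 4 higher, adjusted p = 0.703), myeloid progenitor markers (11 tested, 6 higher, adjusted p = 0.971) and mitochondrially encoded genes (9 tested, 6 higher, adjusted p = 0.561). Neutrophil markers passed without knockout replicate 1 (8.6e-05) and wild-type replicate 1 (adjusted p = 0.0062), and S100a8 ranged from 1.10 to 38.8 CPM over the 5 RNA libraries. Erythroid markers (1 tested), mast cell and basophil markers (2), T and NK cell markers (2) and sex-linked genes (4) had too few tested members for a set test, and none of these members passed adjusted over the list alone in edgeR, with 1 sex-linked gene at an unadjusted p under 0.05 and called by DESeq2.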
